A study of Mus musculus with 12 samples.

How the data were processed

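Polyadenylated RNA was profiled by Smart-seq2 in C57BL/6 mouse oocytes at the germinal vesicle (GV) stage and in embryos at the 1-cell and 2-cell stages, from wild-type (WT) mice and from mice with a Pabpn1l knockout (KO). Each library was made from 10 oocytes or embryos, and the 12 libraries formed 6 groups of 2, 1 group for each stage and genotype. Per the labels, oocytes were collected in vivo and embryos were grown in culture. The labels do not state whether KO refers to the genotype of the mother, of the embryo or of both, nor how the mice were mated. They also do not state whether libraries of a group came from separate animals or pools, so p-values measure the spread between these samples, which may be technical. No sample lacked a group.

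The authors deposited 1 table of FPKM values (fragments mapped per kilobase of transcript, scaled to all mapped fragments of a library), with 1 column for each library. Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse genome build mm9 were used. Per the labels' protocols, complementary DNA was primed with oligo-dT and ERCC spike-in RNA was present in the lysis buffer. The table held 11298 complete entries in alphabetical order from 0610007C21Rik to Zc3h14, and 1 last entry with 1 of 12 values, which was left out. Genes later in the alphabet, such as those of the Zfp, Zp and Zscan4 families, were not analysed here. The table held 0 ERCC entries and 0 mitochondrially encoded genes. No value was below 1 FPKM, and 1 FPKM is called the floor below. A value at the floor says only that the level was at or under 1 FPKM on the deposited scale, and a fold change against a group at the floor has no fixed size.

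The deposited FPKM columns were on different scales. In each of the 8 embryo columns, 100% of the values above the floor were whole multiples of a 6-digit FPKM value times 1 number per library with 9 decimals, at a tolerance of 0.01 of the last digit. These library factors were 0.269 and 0.212 in WT 1-cell, 0.432 and 0.552 in KO 1-cell, 0.116 and 0.123 in WT 2-cell and 0.13 and 0.121 in KO 2-cell embryos. The factor was 1 in the 4 oocyte libraries. What the authors based the factor on is not stated in the sources used here, and no ERCC value was used here. The deposited values were therefore kept as the primary scale, and every comparison was repeated on values divided by the factor, called FPKM before the factor, with the highest floor of the stage applied to all libraries of that stage. FPKM carry no read counts, so the depth of each library is unknown and no counting interval is given.

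Values were analysed as log2(FPKM + 1), so fold changes on this scale understate the change of genes with low values. Linear models were fitted with limma 3.58.1 in R 4.3.3 with all 12 libraries in 1 fit and an intensity trend in the moderated variance. Contrasts were KO against WT at each stage, WT 1-cell against WT GV, WT 2-cell against WT 1-cell, and the differences of the stage transitions between genotypes (interactions). Two-sided p-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Values after ± are standard deviations (SD, n = 2) beside FPKM and standard errors (SE) beside log2 fold changes. A minimum of 1 FPKM in at least 2 libraries had been planned and left out no gene, because of the floor. The 22 gene lists were tested as sets with camera at a preset correlation of 0.01 and again with an estimated correlation. The set of mitochondrially encoded transcripts had 0 members, which left 21 lists, and p-values were adjusted over the lists of a contrast.

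The 22 lists comprised the poly(A)-binding protein family, deadenylation and mRNA decay machinery, oocyte-specific and maternal-effect genes, meiotic cell cycle and spindle checkpoint genes, translational control and cytoplasmic polyadenylation genes, and nuclear cleavage and polyadenylation factors. They further comprised 2-cell-stage transient genes, nucleolar and ribosome biogenesis genes, cytoplasmic ribosomal proteins, translation initiation and elongation factors, proteasome subunits, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded transcripts, histone genes, chromatin modifiers, embryonic lineage regulators, p53 targets and apoptosis genes, and early-response and heat-shock genes. Markers of cumulus and granulosa cells, of sperm, and of blood and immune cells, and common reference genes, completed them. Transcripts were also sorted into classes from 1 WT replicate at a time, and the KO effect was then measured against the other WT replicate, which gave 4 combinations with the KO libraries. Ratios between stages were taken of FPKM + 1. Lost early required at least 5 FPKM in GV oocytes and a 4-fold or larger fall to the 1-cell stage. Lost late required at least 5 FPKM, a fall of less than 2-fold to the 1-cell stage and a 4-fold or larger fall from there to the 2-cell stage. Gained required at least 5 FPKM in 2-cell embryos and a 4-fold or larger rise over both earlier stages, and kept required at least 5 FPKM in GV oocytes and both ratios within 2-fold.

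The genes named in the text followed a fixed rule. Pabpn1l and Btg4 were given in every group. For KO against WT, the 8 largest rises and the 8 largest falls were taken among called genes whose groups did not overlap and whose higher group had a mean of at least 10 FPKM, without gene models named Gm or LOC plus digits or ending in Rik and without microRNA and small nucleolar RNA names; for WT transitions and interactions 5 were taken in place of 8. From each list, up to 4 members with the largest absolute log2 fold change and a mean of at least 5 FPKM in the higher group were named, called or not. Some genes that this rule selects are not reported here. Any other gene was part of a count of 5 or fewer and was chosen after its values were seen. The groups, tests, lists, classes, naming rule and a set of other settings were fixed before the data were examined. These other settings were a pseudocount of 0.1, a filter at a mean of 5 FPKM, no filter, quantile normalization, median-ratio size factors, a fit of only the groups compared, no intensity trend, the replicate number as a block, leaving out each library in turn, and classes with a 2-fold threshold, with at least 20 FPKM or with both WT replicates. Scaling to ERCC RNA had been planned and was not run. Chosen after seeing the data were the values before the factor, no pseudocount, genes above the floor in every library of the contrast, overlaps of genes above the floor at both stages, and classes restricted to genes whose longest transcript in GENCODE M21 had at least 2000 bases. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

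The tests were tested on simulated data with the real group means of 11298 genes and 200 genes changed by known folds. With 1 spread per gene, as the model assumes, the fit recovered 43, 30 and 19 of 100 genes changed 2-fold and 94, 87 and 87 of 100 genes changed 4-fold at the GV, 1-cell and 2-cell stages, and false calls made up 5.5%, 2.5% and 6.2% of all calls. With each stage's own spread and the floor, they made up 62.3%, 37.1% and 21.2%. With no gene changed, this simulation gave 272, 1 and 8 calls in the same order, so calls between oocytes are unreliable. In further simulations with no gene changed, the GV stage gave 1 call with 1 spread per gene and the floor, 157 with each stage's own spread and no floor, and 241 with both, and with changed genes false calls made up 27.9%, 60.6% and 68% of all calls there. Of the 21 set tests, 0 were called at any stage with no gene changed. Genes were simulated independently, so correlated lists were not tested.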

Results

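The data comprised FPKM values of 11298 genes in 12 Smart-seq2 libraries of WT and Pabpn1l KO mice, with 2 libraries for each of GV oocytes, 1-cell embryos and 2-cell embryos. The design asks how the transcriptome changes from the oocyte to the 2-cell embryo and how it differs without Pabpn1l, which encodes a poly(A)-binding protein of oocytes and early embryos. Summed over genes, WT GV oocytes held 5.893e+05 ± 1.425e+04 FPKM (SD, n = 2), WT 1-cell embryos 1.129e+05 ± 1.992e+04 and WT 2-cell embryos 5.643e+04 ± 4067, or 19.2% and 9.58% of the oocyte total. KO GV oocytes held 6.045e+05 ± 2822 FPKM. KO 1-cell embryos held 2.61e+05 ± 3.449e+04, or 43.2% of the oocyte total, and KO 2-cell embryos 6.382e+04 ± 381.1, or 10.6%. The KO total was 2.31 times the WT total at the 1-cell stage and 1.13 times at the 2-cell stage. These ratios follow the library factors of the deposited table. Summed over genes above the floor, the totals of the 12 libraries before the factor lay between 413054 and 605495. Genes at the floor numbered 928.5 ± 40.31 in WT and 1019 ± 36.77 in KO oocytes. They numbered 4762 ± 246.8 and 3058 ± 441.9 in 1-cell embryos, and 5342 ± 311.8 and 6374 ± 264.5 in 2-cell embryos. Replicates correlated at Pearson's r of 0.969 to 0.991 across genes on the log2 scale, where genes are not independent replicates.

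**Figure D1:**
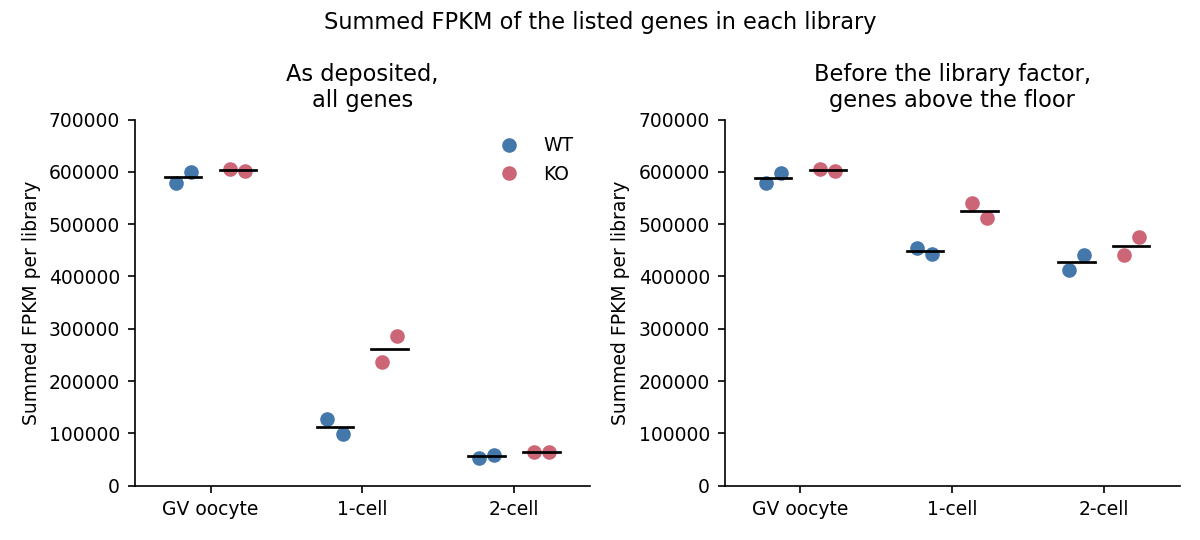
Summed FPKM (vertical axis) for each group of GV oocytes, 1-cell and 2-cell embryos (horizontal axis), over all genes as deposited at left and over genes above the floor before the library factor at right; points are the 2 libraries of a group and lines their means. As deposited, the KO 1-cell libraries at 236619 and 285396 FPKM lie above the WT ones at 127008 and 98843. The sums before the factor lie between 413054 and 605495 in all libraries.

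Pabpn1l transcripts were depleted in KO oocytes. The WT GV libraries held 220.1 and 203.9 FPKM of Pabpn1l and the KO GV libraries 7.229 and 4.979. This is a 34.7-fold difference of means (log2 fold change −4.92 ± 0.27 SE, limma adjusted p = 0.000288). In 1-cell embryos Pabpn1l measured 16.38 and 12.21 FPKM in WT and 2.575 and 4.546 in KO (log2 fold change −1.77 ± 0.27, adjusted p = 0.00109). In 2-cell embryos it was near the floor in every library, at 1.18 and 1 FPKM in WT and 1.002 and 1.902 in KO. No difference passed the test (0.21 ± 0.27, adjusted p = 0.987), except with quantile normalization (0.96, adjusted p = 0.0449). The oocyte and 1-cell libraries thus carried the Pabpn1l levels that their labels name, whereas Pabpn1l cannot check the labels at the 2-cell stage. Btg4, an adaptor that recruits the CCR4-NOT deadenylase to maternal mRNA, measured 2099 ± 69.3 FPKM in WT and 2232 ± 82.5 in KO oocytes, with no difference past the test (0.09 ± 0.23, adjusted p = 1). Btg4 was higher in KO 1-cell embryos as deposited, at 2192 ± 128 against 889 ± 276 FPKM (1.34 ± 0.23, adjusted p = 0.00195). Before the factor this difference did not pass (0.31, adjusted p = 0.475). In 2-cell embryos Btg4 was 2.77 times as high in KO, at 631 ± 27.3 against 228 ± 40.1 FPKM (1.47 ± 0.23, adjusted p = 0.00202), also before the factor (1.40, adjusted p = 0.00056).

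**Figure D2:**
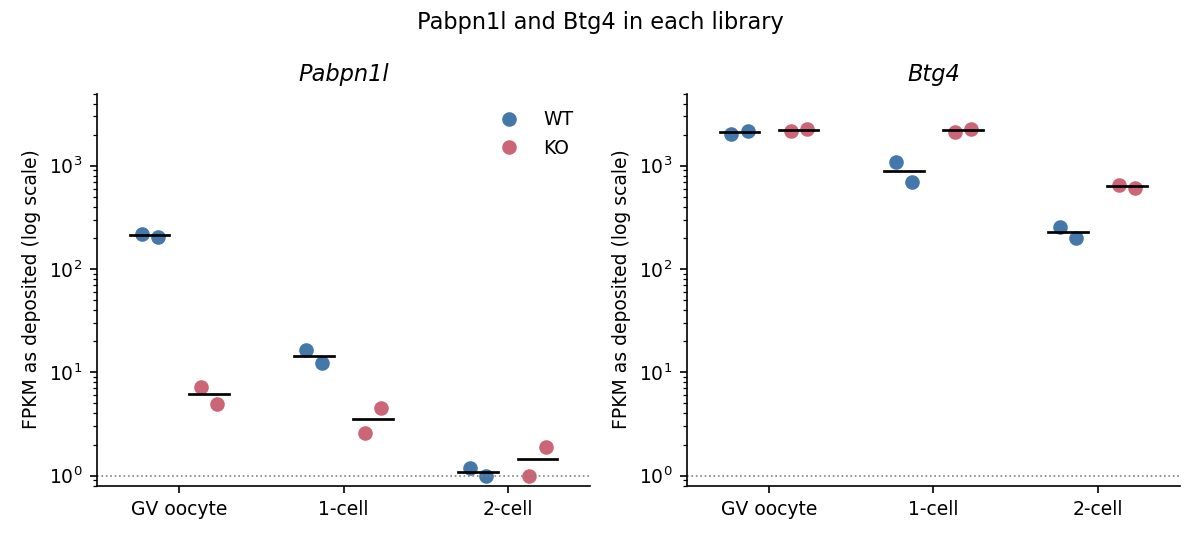
FPKM as deposited on a log axis (vertical) for Pabpn1l and Btg4 in WT and KO GV oocytes, 1-cell and 2-cell embryos (horizontal axis); points are the 2 libraries of a group, lines their means and the dotted line the floor of 1 FPKM. Pabpn1l falls from 212 FPKM in WT to 6.10 FPKM in KO oocytes, and Btg4 is 631 FPKM in KO against 228 FPKM in WT 2-cell embryos.

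In GV oocytes few differences other than Pabpn1l stood out. Cox4i2, an isoform of a cytochrome c oxidase subunit, was 2.32 times as high in KO, at 11.1 ± 0.249 against 4.77 ± 0.161 FPKM (log2 fold change 1.06 ± 0.11 SE, limma adjusted p = 0.00262). Fam25c was lower, at 16.5 ± 2.67 against 31.5 ± 6.12 FPKM (−0.89 ± 0.16, adjusted p = 0.0318). With quantile normalization neither passed (0.66, adjusted p = 1, and −0.72, adjusted p = 0.5), and 1 gene was called higher and 1 lower in all. In all, 66 genes were called higher and 117 lower in KO, of which 2 and 3 changed at least 2-fold. Besides Cox4i2 and Pabpn1l these were Hamp2, which encodes a hepcidin (1.21), Anpep, which encodes aminopeptidase N (−1.15, KO at the floor), and Gm9781 (−1.38), chosen after their values were seen. Of the fixed lists, 83 oxidative phosphorylation genes had a median log2 fold change of 0.13, with 1 member called, Cox4i2, also when adjusted over the list alone (camera adjusted p = 4.61e-05, and adjusted p = 0.962 with an estimated correlation). The 85 ribosomal proteins had a median of 0.12 with 0 members called, 0 also when adjusted over the list alone and 0 at an unadjusted limma p under 0.05 (camera adjusted p = 0.00295, and adjusted p = 0.962 with an estimated correlation). The 17 early-response and heat-shock genes had a median of 0.11 with 1 member called, the immediate early gene Ier2 (0.34, camera adjusted p = 0.00295, and adjusted p = 0.962 with an estimated correlation). With quantile normalization the camera adjusted p was 0.237 for ribosomal proteins and 0.0949 for early-response genes. The poly(A)-binding family had 1 of 8 members called, Pabpn1l, with a median of −0.04 and a mean of −0.63. The oocyte-specific and maternal-effect list had 0 of 41 called, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. Among 38 histone genes Hist4h4 (0.32) was called higher and the linker histone gene Hist1h1c (−0.50) lower. Among 11 cumulus and granulosa markers the follicle-stimulating hormone receptor gene Fshr (0.66) was called higher. Besides these, 0 members of any other list were called, sperm and blood markers included. The number of calls is no larger than simulated data with no changed gene gave, 272. It fell to 0 higher and 2 lower in limma among genes with a mean of at least 5 FPKM (61 genes at an unadjusted p under 0.05). Leaving out 1 library raised it, to 151 and 370 without WT replicate 1, 196 and 423 without WT replicate 2, 360 and 433 without KO replicate 1 and 351 and 328 without KO replicate 2. Without KO replicate 2 the call of Fam25c ended as well (−0.73, adjusted p = 0.0518). The call of Anpep ended without WT replicate 2 (−1.07, adjusted p = 0.0632), and that of Gm9781 without WT replicate 1 (−1.33, adjusted p = 0.0849), WT replicate 2 (−1.42, adjusted p = 0.058) or KO replicate 1 (−1.28, adjusted p = 0.0645).

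At the 1-cell stage most detected transcripts were higher in KO as deposited. The 45S pre-ribosomal RNA Rn45s was at the floor in both WT libraries and at 4062 ± 1100 FPKM in KO (limma adjusted p = 6.16e-06). The histone H2B gene Hist1h2bc rose from 3.50 ± 2.16 to 166 ± 12.2 FPKM (log2 fold change 5.30 ± 0.29 SE, adjusted p = 1.15e-05). The cytochrome c oxidase subunit gene Cox7c rose from 1.66 ± 0.934 to 94.7 ± 1.84 (5.21 ± 0.34, adjusted p = 1.96e-05) and the proteasome subunit gene Psma5 from 6.49 ± 2.51 to 151 ± 10.8 (4.39 ± 0.24, adjusted p = 1.03e-05). Tm2d1 (4.53 ± 0.32), the complex I gene Ndufb3 (4.36 ± 0.25), the mitochondrial import gene Mtx2 (4.31 ± 0.39) and Lsm5 (4.30 ± 0.33), which encodes an Sm-like protein of RNA decay and splicing complexes, rose as well. Each of these genes was also called higher before the factor, with log2 fold changes of 3.32 for Lsm5 to 4.72 for Cox7c, apart from Rn45s and Mtx2, which were at the common floor in both WT libraries on that scale. Genes lower in KO were the vacuolar ATPase subunit gene Atp6v1g1, at 13.6 ± 0.709 against 29.5 ± 6.24 FPKM (−1.05 ± 0.17, adjusted p = 0.00139), and the endoplasmic reticulum translocation gene Sec62, at 5.81 ± 0.539 against 12.8 ± 0.993 (−1.01 ± 0.18, adjusted p = 0.00217). Also lower were the superoxide dismutase gene Sod1, at 83.5 ± 8.53 against 139 ± 22.3 (−0.72 ± 0.19, adjusted p = 0.0103), Frg1 (−0.96 ± 0.30, adjusted p = 0.0254) and Cox5a (−0.57 ± 0.20, adjusted p = 0.0426). Besides Pabpn1l, Atp6v1g1 and Sec62, the genes at least 2-fold lower were Anpep (KO at the floor, adjusted p = 0.00089) and the cell cycle kinase gene Cdk1 (−1.24, adjusted p = 0.00178), chosen after their values were seen. Before the factor these genes were called lower as well, at −2.09 for Atp6v1g1, −2.07 for Sec62, −2.02 for Frg1, −1.94 for Cdk1, −1.75 for Sod1 and −1.60 for Cox5a. In all, 5950 genes were called higher and 11 lower, 2736 and 5 of them at least 2-fold. Over 6227 genes above the floor in all 4 libraries the median log2 ratio of KO to WT was 1.04, a 2.06-fold shift, and before the factor it was 0.01. Relative to that shift the direction was mixed. Before the factor 831 genes were higher and 255 lower (508 and 61 at least 2-fold), of which 842 were called in the same direction as on the deposited scale and 19 in the opposite one. The share of calls that were higher was 99.8% as deposited, 76.5% before the factor, 69.6% with median-ratio size factors and 43.8% with quantile normalization. Without WT replicate 2 the number called higher was 3422, without KO replicate 2 it was 3902. Without WT replicate 1 the number called lower was 6. Calls ended for Frg1 without WT replicate 1 (−0.81, adjusted p = 0.126), WT replicate 2 (−1.11, adjusted p = 0.0606) or KO replicate 2 (−0.43, adjusted p = 0.158). They also ended for Sod1 without WT replicate 1 (−0.56, adjusted p = 0.053) or KO replicate 2 (−0.62, adjusted p = 0.0707) and for Cox5a without WT replicate 1 (−0.25, adjusted p = 0.263), KO replicate 1 (−0.57, adjusted p = 0.0976) or KO replicate 2 (−0.56, adjusted p = 0.142).

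Most proteasome and oxidative phosphorylation genes rose in KO 1-cell embryos as deposited. Of 34 proteasome subunit genes 31 rose, 0 fell and 3 did not pass (33 rose when adjusted over the list alone). Examples were Psmb1 (log2 fold change 3.98 ± 0.24 SE), Psmb7 (3.30 ± 0.20) and Psma1 (3.26 ± 0.24). Their median was 1.53 as deposited and 0.64 before the factor, where 15 were higher and 0 lower (camera adjusted p = 5.02e-08 and 3.93e-11). Of 83 oxidative phosphorylation genes 66 rose and 1 fell, Cox5a (68 and 1 adjusted over the list alone), with Cox7b (3.83 ± 0.35) and the succinate dehydrogenase gene Sdhd (3.52 ± 0.24) as examples. The median was 1.36 as deposited and 0.55 before the factor, where 30 were higher and 4 lower (camera adjusted p = 2.88e-07 and 3.45e-08). Of 85 ribosomal protein genes 60 rose and 25 did not pass (61 adjusted over the list alone). Examples were Rpl5 (4.21 ± 0.19), Rpl18 (3.91 ± 0.22) and Rpl32 (3.37 ± 0.17). The median was 1.14 (camera adjusted p = 0.000143), and before the factor 18 were higher and 2 lower (camera adjusted p = 0.00136). With an estimated correlation the adjusted p was 0.578 for these lists as deposited. Transcript length was not tested for these lists. Genes called at least 2-fold higher before the factor had a median length of 2017 bases, against 3078 for all genes with a length. Oocyte-specific and maternal-effect genes rose in 35 of 41 cases (37 adjusted over the list alone), including the NLR gene Nlrp2 (2.72 ± 0.22), Zar1l (2.38 ± 0.22), the oocyte growth factor gene Gdf9 (2.34 ± 0.35) and the oocyte transcription factor gene Nobox (2.24 ± 0.34). With quantile normalization the calls of Gdf9 (0.86, adjusted p = 0.0877) and Nobox (0.96, adjusted p = 0.0524) ended. Their median was 1.03 (camera adjusted p = 0.000928, and adjusted p = 0.578 with an estimated correlation). Before the factor 9 were higher and 1 lower (camera adjusted p = 0.315). Deadenylation and mRNA decay genes rose in 33 of 39 cases (34 adjusted over the list alone) with a median of 0.92 (camera adjusted p = 0.0137, or 0.887 before the factor with 1 higher and 0 lower, and adjusted p = 0.578 with an estimated correlation). The antiproliferative genes Tob1 (WT at the floor, KO 6.23 ± 0.447 FPKM) and Tob2 (1.74 ± 0.22) and the deadenylase gene Parn (1.41 ± 0.30) had the largest changes. Of these, that of Tob1 alone was also called before the factor. Translational control genes rose in 23 of 29 cases (26 adjusted over the list alone, median 0.98, camera adjusted p = 0.0137) and translation factors in 44 of 61 (45 adjusted over the list alone, median 0.86, camera adjusted p = 0.0181). Neither kept its camera call before the factor (0.815 and 0.682). For these lists, too, adjusted p = 0.578 with an estimated correlation.

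Of the poly(A)-binding family at the 1-cell stage, 5 of 8 members rose and Pabpn1l fell as deposited, whereas 1 rose and Pabpn1l fell before the factor and with quantile normalization. The largest rise was that of Paip2, a regulator of poly(A)-binding protein, from 9.80 ± 2.38 to 200 ± 0.212 FPKM (4.24 ± 0.19, or 3.31 before the factor). Those of Paip2b (1.19) and Pabpc1l (1.17) did not pass before the factor (0.18 and 0.22), and that of Paip2b turned with quantile normalization (−0.08). These 2 calls also ended without WT replicate 2 (0.98, adjusted p = 0.119, and 1.18, adjusted p = 0.0932) or KO replicate 2 (0.98, adjusted p = 0.123, and 0.59, adjusted p = 0.181), and that of Pabpc1l without WT replicate 1 (1.16, adjusted p = 0.081). Meiotic and spindle checkpoint genes rose in 26 of 39 cases and fell in 1, Cdk1, with the kinase genes Mos (2.98 ± 0.20) and Bub1 (2.14 ± 0.18) as examples, but before the factor 2 were higher and 5 lower. Rises without a camera call were also counted as deposited for 37 of 60 nucleolar genes (10 higher and 3 lower before the factor), 22 of 30 cleavage and polyadenylation factors (5 and 0), 30 of 48 chromatin modifiers (2 and 1) and 8 of 22 lineage regulators (0 and 0). They were counted for 9 of 25 p53 targets (0 and 0 before the factor), 6 of 17 early-response genes (1 and 0), 12 of 19 reference genes (3 and 0) and 13 of 38 histone genes (3 and 0). The histone genes had a median of 0.30 and a mean of 0.61 although camera ranked them below other genes (adjusted p = 0.194). Of 27 2-cell-stage transient genes 20 were at the floor in all 4 libraries and 3 rose, D5Ertd577e (3 ± 0.16), Fbxo15 (1.13) and Cml2 (0.95), of which the last 2 did not pass before the factor (0.24 and 0.08). The median was thus 0, the mean 0.24 and the camera direction down (adjusted p = 0.000143, and adjusted p = 0.578 with an estimated correlation). Marker genes of other cells were sparse. Cumulus and granulosa markers were at the floor for 8 of 11 genes, and the estrogen receptor gene Esr2 (0.81) and the aromatase gene Cyp19a1 (0.76) were called higher, both turning to lower values before the factor (−0.11 and −0.16). For this list the median was 0, the mean 0.15 and the camera direction down (adjusted p = 0.0137, and adjusted p = 0.578 with an estimated correlation). Of 6 sperm markers Ldhc (0.72) and of 10 blood markers S100a8 (0.37) and Pecam1 (0.80) were called higher, the first 2 with WT at the floor. Their values were 0.05, 0 and −0.04 before the factor. Leaving out 1 library ended several of these calls. Without WT replicate 2 the adjusted p was 0.0939 for Fbxo15 (0.85), 0.0995 for Cml2 (0.60), 0.0844 for Esr2 (0.50), 0.059 for Cyp19a1 (0.61), 0.0605 for Ldhc (0.72) and 0.143 for Pecam1 (0.70). Without KO replicate 2 it was 0.0831 for Fbxo15 (0.94), 0.0915 for Cml2 (0.68), 0.0707 for Esr2 (0.68), 0.0745 for Ldhc (0.51) and 0.134 for Pecam1 (0.35). Without WT replicate 1 it was 0.0567 for Pecam1 (0.90).

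In 2-cell embryos the KO differed from WT in both directions by large factors. Rn45s was again at the floor in both WT libraries and at 1464 ± 197 FPKM in KO (limma adjusted p = 1.07e-06). Hist1h2bc was at the floor in WT and at 29.0 ± 6.55 FPKM in KO (adjusted p = 2.88e-05). Lsm5 rose from 8.41 ± 1.12 to 172 ± 20.2 FPKM (log2 fold change 4.20 ± 0.33 SE, adjusted p = 3.44e-05). Further rises were Tm2d1 by 4.03 ± 0.32, Plac1l by 3.83 ± 0.22, the calcium-binding protein gene Pdcd6 by 3.54 ± 0.33, Lgsn by 3.28 ± 0.21 and Ndufb3 by 3.27 ± 0.25 on the log2 scale. The largest fall was that of the tetraspanin gene Cd63, from 38.7 ± 13 to 1.29 ± 0.408 FPKM (−4.09 ± 0.20, adjusted p = 2.9e-06). Next were the nucleoside diphosphate kinase gene Nme2, from 64.0 ± 8.23 to 3.38 ± 0.811 (−3.90 ± 0.24, adjusted p = 7.36e-06), the homeobox gene Obox3 (−3.70 ± 0.40), Cdk2ap1 (−3.67 ± 0.31), Guca1a (−3.64 ± 0.14) and the splicing gene Snrpc of the U1 particle, from 37.6 ± 8.29 to 2.70 ± 1.5 (−3.43 ± 0.26). H47 also fell (−3.39 ± 0.32), and the alkaline phosphatase gene Alppl2 fell from 19.9 ± 4.66 FPKM to the floor. In all, 854 genes were called higher and 1357 lower, 446 and 807 of them at least 2-fold. The median log2 ratio over 3949 genes above the floor was 0.13 as deposited and 0.05 before the factor. The share of calls that were higher was 38.6% as deposited and 37.3% before the factor (1194 higher and 2006 lower), against 55.5% with quantile normalization (2705 and 2169) and 53.5% among genes above the floor in every library (914 and 796). Leaving out WT replicate 1 gave 464 higher, WT replicate 2 525 higher and 834 lower, and KO replicate 2 562 higher and 878 lower. All genes named here kept their direction and call before the factor.

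Many ribosomal protein genes and part of the ribosome biogenesis genes fell in KO 2-cell embryos. Of 85 ribosomal protein genes 58 fell, 3 rose and 24 did not pass (63 and 5 adjusted over the list alone), with a median log2 fold change of −1.34 (camera adjusted p = 5.6e-17, and adjusted p = 0.645 with an estimated correlation). Rpl24 fell by −2.79 ± 0.39 SE. Before the factor 62 fell and 3 rose. Of 60 nucleolar and ribosome biogenesis genes 29 fell and 3 rose (36 and 3 adjusted over the list alone). Falls included Nhp2 (−3.06 ± 0.21), the RNA polymerase subunit gene Polr1c (−2.86 ± 0.19) and Rrp9 (8.42 ± 0.55 FPKM to the floor), with a median of −0.59 (camera adjusted p = 7.23e-10, and adjusted p = 0.645 with an estimated correlation). Of 27 transient genes of the 2-cell stage 13 fell and 1 rose (14 and 1 adjusted over the list alone). Sp110 fell from 57.4 ± 2.5 to 6.71 ± 1.83 FPKM (−2.94 ± 0.19), Slc34a2 by −2.62 ± 0.13, Fbxo15 by −2.36 ± 0.30 and Pramel7 by −2.16 ± 0.12 (median −0.63, camera adjusted p = 2.12e-08, and adjusted p = 0.645 with an estimated correlation). Oocyte-specific and maternal-effect genes went the other way, with 16 of 41 rising and 3 falling (20 and 4 adjusted over the list alone). Rises included Obox1 (2.22 ± 0.26), Nlrp4f (2.2 ± 0.22) and Obox2 (2.03 ± 0.24), with a median of 0.73 (camera adjusted p = 6.9e-07, and adjusted p = 0.645 with an estimated correlation). Proteasome genes fell in 16 of 34 cases and rose in 3 (16 and 4 adjusted over the list alone, median −0.61, camera adjusted p = 0.00263, and adjusted p = 0.667 with an estimated correlation), including Psmb5 (10.1 ± 2.65 FPKM to the floor) and Psma3 (−2.14 ± 0.21). Meiotic and spindle checkpoint genes fell in 14 of 39 and rose in 4 (14 and 5 adjusted over the list alone, median −0.30, camera adjusted p = 0.0305, and adjusted p = 0.667 with an estimated correlation), with Cdk1 (−2.51 ± 0.21), Cdca8 (−2.33 ± 0.21) and Aurka (−2.04 ± 0.27). Cleavage and polyadenylation factors fell in 12 of 30 and rose in 1 (14 and 3 adjusted over the list alone, median −0.23, camera adjusted p = 0.0252, and adjusted p = 0.667 with an estimated correlation), with Nudt21 (−1.89 ± 0.19) and Cstf3 (6.40 ± 1.53 FPKM to the floor). Translation factors fell in 16 of 61 and rose in 3 (17 and 6 adjusted over the list alone, median −0.28, camera adjusted p = 0.0252, and adjusted p = 0.667 with an estimated correlation), with Eif4a3 (−2.23 ± 0.25) and Eif3h (−1.93 ± 0.20) lower and Eif1b (1.72 ± 0.22) higher.

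Translational control genes rose in 4 of 29 cases in KO 2-cell embryos, namely the germ cell RNA-binding protein gene Dazl, from 9.12 ± 0.626 to 66.4 ± 16.3 FPKM (2.72 ± 0.23), Lsm14b (1.48), Lsm14a (1.03) and Gtsf1 (0.78). In this list 0 fell, with 4 rising when adjusted over the list alone and a median of 0.18. Their camera adjusted p was 0.00557 (0.0582 with quantile normalization, and adjusted p = 0.667 with an estimated correlation). In the poly(A)-binding family Pabpc1 (−1.76 ± 0.26), Pabpn1 (−1.38 ± 0.24) and Pabpc4 (−1.07) fell, and the interacting proteins Paip1 (1.20) and Paip2 (1.04) rose. Deadenylation and mRNA decay genes included 5 of 39 that rose, Btg4 and the deadenylase gene Cnot7 (1.28 ± 0.26) among them, and 2 that fell (6 and 6 before the factor). Lineage and pluripotency regulators included 7 of 22 that fell and 2 that rose, with Dppa4 (−2.93 ± 0.18) and Dppa2 (−1.44 ± 0.21) lower. Pou5f1 did not pass (−0.86 ± 0.32, adjusted p = 0.108), although it did before the factor (−1.04, adjusted p = 0.036). Oxidative phosphorylation genes split into 15 of 83 that rose and 23 that fell (camera adjusted p = 0.375). Of histone genes 5 rose and 3 fell of 38, with a median of 0, a mean of 0.10 and no camera call. Chromatin modifiers split into 5 and 6 of 48, with a median of 0, a mean of −0.08 and the camera direction up (adjusted p = 0.94). Of 25 p53 targets 6 fell, and of 19 reference genes 7 fell. The heat-shock genes Hspb1 (−1.62), Hspa5 (−1.26) and Hsph1 (−1.10) were the 3 of 17 early-response genes that fell, while with quantile normalization 7 rose and 3 fell. Markers of other cells moved little. Of 11 cumulus markers Vim (0.31) was called higher, of 6 sperm markers Tsga8 (−0.37) lower, and of 10 blood markers Lyz2 (0.81) and Tyrobp (0.37) higher, each with the lower group at the floor. The blood markers had a median of 0.06 (camera adjusted p = 0.0372, 0.085 before the factor, and adjusted p = 0.645 with an estimated correlation). Calls ended without WT replicate 1 for Pabpc4 (−1.02, adjusted p = 0.108), Gtsf1 (0.85, adjusted p = 0.0542), Lsm14a (0.90, adjusted p = 0.0519), Hspa5 (−1.50, adjusted p = 0.0736) and Tyrobp (0.37, adjusted p = 0.0573). They ended without WT replicate 2 for Pabpc4 (−1.12, adjusted p = 0.0909), Cnot7 (1.07, adjusted p = 0.0892), Gtsf1 (0.72, adjusted p = 0.104), Hspa5 (−1.01, adjusted p = 0.242), Hspb1 (−1.60, adjusted p = 0.051) and Tyrobp (0.37, adjusted p = 0.066). Without KO replicate 1 that of Pabpc4 ended (−0.91, adjusted p = 0.119). Without KO replicate 2 those of Cnot7 (1.19, adjusted p = 0.0631), Gtsf1 (0.52, adjusted p = 0.096) and Hspa5 (−0.80, adjusted p = 0.218) ended.

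**Figure D3:**
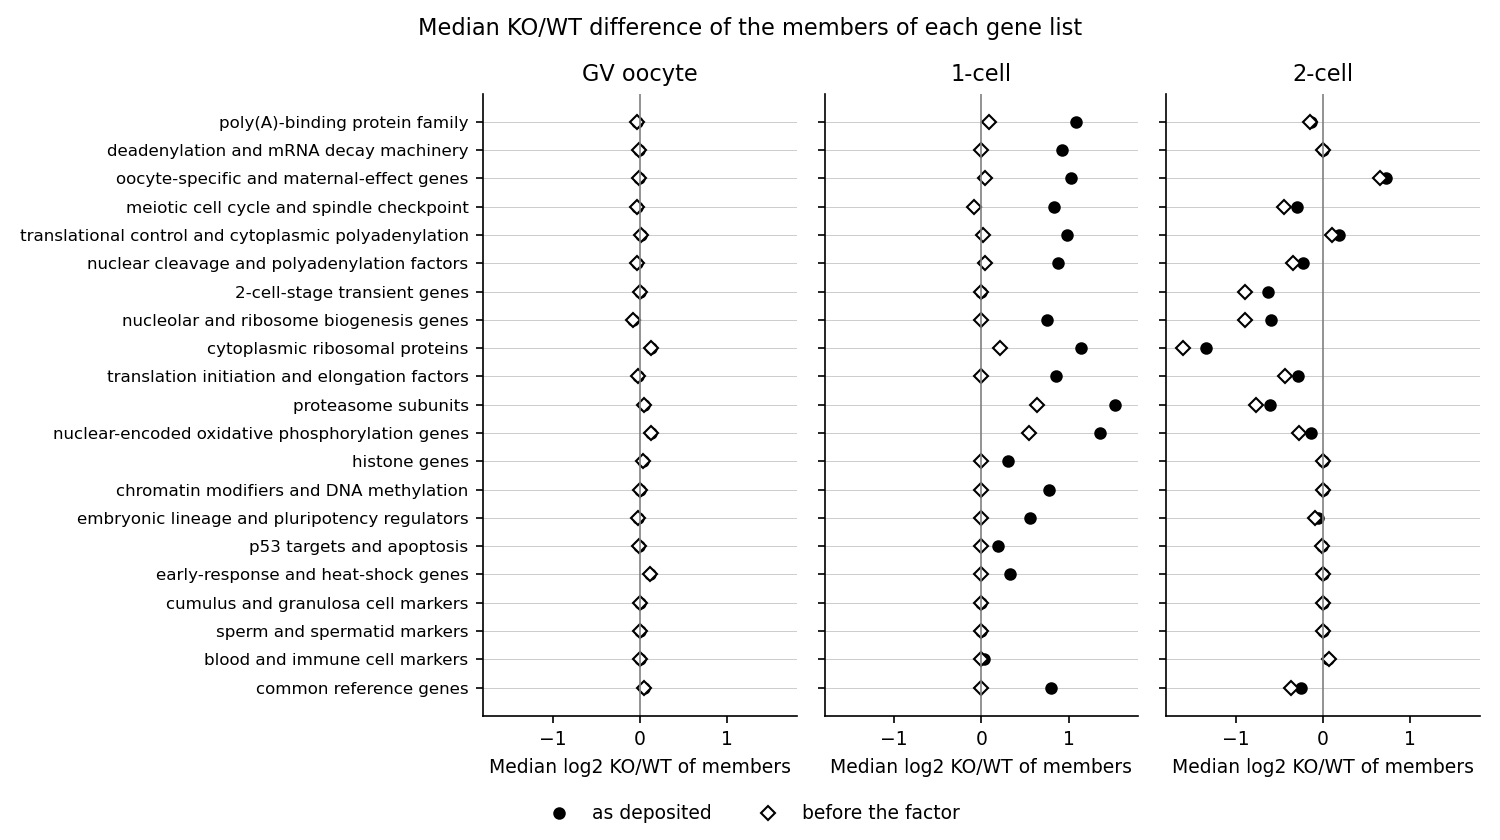
Median log2 ratio of KO to WT over the members of each fixed gene list (horizontal axis) in GV oocytes, 1-cell and 2-cell embryos, with lists on the vertical axis; filled circles are values as deposited and open diamonds values before the library factor. At the 1-cell stage proteasome subunits have a median of 1.53 as deposited and 0.64 before the factor, and at the 2-cell stage ribosomal proteins have a median of −1.34.

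From GV oocytes to 1-cell embryos, WT transcripts encoding ribosomal, mitochondrial and proteasome proteins fell furthest. Rn45s went from 5053 ± 1420 FPKM to the floor in both libraries (limma adjusted p = 6.32e-08). Cox7c fell by a log2 fold change of −7.83 ± 0.34 SE (−5.93 before the factor) and the copper chaperone gene Cox17 by −7.41 ± 0.20 (−5.73 before the factor). Rps27 fell from 411 ± 1.24 FPKM to the floor (adjusted p = 0.00589), a call that did not hold before the factor (adjusted p = 0.0977) or with median-ratio size factors (adjusted p = 0.0991). In the 2 KO oocyte libraries Rps27 measured 298.9 and 1 FPKM, and this spread enters the shared fit. Of 85 ribosomal protein genes 84 fell (84 adjusted over the list alone), with a median of −4.84 (camera adjusted p = 4.33e-10, and adjusted p = 0.507 with an estimated correlation). Before the factor 77 fell and 1 rose. Of 83 oxidative phosphorylation genes 82 fell (82 adjusted over the list alone). Ndufb4 fell by −6.50 ± 0.19, and the median was −4.09 (camera adjusted p = 3.33e-09, adjusted p = 0.375 with an estimated correlation, 64 lower and 3 higher before the factor). Proteasome genes fell in 34 of 34 cases (34 adjusted over the list alone), with Psmb1 at −6.38 ± 0.24 and a median of −3.61 (camera adjusted p = 6.32e-05, adjusted p = 0.529 with an estimated correlation, 25 lower before the factor). The nucleolar list (58 of 60, median −2.37, camera adjusted p = 0.00774, adjusted p = 0.713 with an estimated correlation, 27 lower and 1 higher before the factor) and translation factors (59 of 61, camera adjusted p = 0.00976, adjusted p = 0.701 with an estimated correlation, 27 lower and 3 higher before the factor) fell too. Oocyte-specific and maternal-effect genes fell in 39 of 41 cases (16 lower and 4 higher before the factor), including the plasminogen activator gene Plat (−5.75 ± 0.32) and the oocyte transcription factor gene Figla (70.7 ± 8.26 FPKM to the floor). The meiotic kinase gene Mos (−7.01 ± 0.20), the polyadenylation factor gene Cpsf4l (−5.41 ± 0.22) and Pabpn1l (−3.81 ± 0.27) fell as well. Btg4 fell from 2099 ± 69.3 to 889 ± 276 FPKM (−1.27, adjusted p = 0.000596). This direction turned before the factor (0.79, adjusted p = 0.0797), with median-ratio size factors (0.78, adjusted p = 0.094) and with quantile normalization (0.56, adjusted p = 0.00615).

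Falls from GV oocytes to WT 1-cell embryos were also counted for 36 of 39 deadenylation, 38 of 39 meiotic, 26 of 29 translational control, 27 of 30 cleavage and polyadenylation, 41 of 48 chromatin and 7 of 8 poly(A)-binding genes, for 19 of 19 reference genes and for 4 of 6 sperm markers, without a camera call. Before the factor the lower and higher numbers of these lists were 6 and 10, 12 and 5, 5 and 7, 10 and 1, 4 and 13, 3 and 2, 8 and 2, and 2 and 0, so the direction turned for deadenylation, translational control and chromatin genes. Histone genes (25 of 38 lower and 1 higher, camera adjusted p = 0.0139), lineage regulators (16 of 22 lower, adjusted p = 0.0139), p53 targets (18 of 25 lower, adjusted p = 0.00787), early-response genes (9 of 17 lower, adjusted p = 0.0062), cumulus markers (4 of 11 lower, adjusted p = 0.00115) and blood markers (4 of 10 lower, adjusted p = 4.48e-05) had medians and means below 0, but camera placed them above other genes. Before the factor these 6 lists had 6 lower and 4 higher, 5 and 2, 1 and 6, 4 and 1, 1 and 0, and 0 and 0. The same held for 2-cell-stage transient genes (8 of 27 lower, median 0, mean −0.73, camera adjusted p = 1.64e-12). With an estimated correlation none of these calls held, and the lowest adjusted p was 0.221. In all, 4 genes were called higher and 9692 lower between WT GV oocytes and WT 1-cell embryos, 7654 of the latter at least 2-fold. This compares with a median log2 ratio of −2.16 (0.224-fold) over 6245 genes as deposited and −0.10 before the factor. Before the factor 979 genes were higher and 2383 lower. The share of higher calls was thus 0% as deposited and 29.1% before the factor, 29% with median-ratio size factors (993 and 2429) and 58.4% with quantile normalization (3775 and 2690). The genes called higher as deposited were the vault RNA Vaultrc5, from the floor to 22.8 ± 5.11 FPKM (adjusted p = 3.72e-06), and 3 chosen after their values were seen. These were Gm12238 (adjusted p = 0.0117) and the small Cajal body RNA Scarna13 (adjusted p = 4.16e-07), both at the floor in oocytes, and the testis and oocyte histone gene Hist1h2ba (1.04, adjusted p = 0.0091). Without WT GV replicate 2 the number called higher was 2. The call of Gm12238 ended without WT GV replicate 1 (adjusted p = 0.0686), WT GV replicate 2 (adjusted p = 0.0687) or WT 1-cell replicate 2 (adjusted p = 0.0577). That of Hist1h2ba ended without WT GV replicate 2 (0.67, adjusted p = 0.105) or WT 1-cell replicate 1 (0.85, adjusted p = 0.0632).

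From the 1-cell to the 2-cell stage WT embryos gained transcripts of ribosomal proteins and 2-cell-stage transient genes, and lost oocyte transcripts. Dcdc2c rose from 1.45 ± 0.114 to 325 ± 145 FPKM (log2 fold change 6.98 ± 0.70 SE, limma adjusted p = 6.03e-05). The metallothionein genes Mt1 and Mt2 rose from the floor to 121 ± 37.4 and 91.8 ± 29.3, Abt1 from the floor to 94.7 ± 28.5, and D17Ertd648e by 5.24 ± 0.67. The G-protein regulator gene Rgs2 fell from 191 ± 34.6 to 1.21 ± 0.0325 FPKM (−6.43 ± 0.16, adjusted p = 1.01e-07). The oocyte homeobox gene Obox2 fell by −5.63 ± 0.24, the oocyte linker histone gene H1foo by −5.06 ± 0.28, the maternal-effect gene Zar1 by −5.02 ± 0.35, Fbxw28 by −4.76 ± 0.20, Pabpn1l by −2.86 ± 0.27 and Btg4 by −1.93 ± 0.23 (−0.94 before the factor). Of 85 ribosomal protein genes 61 rose and 3 fell (64 and 4 adjusted over the list alone). Rises included Rpl23a at 3.68 ± 0.43 and Rps19 from the floor to 24.7 ± 8.77 FPKM (median 1.38, camera adjusted p = 1.26e-25, and adjusted p = 0.467 with an estimated correlation). Of 27 transient genes of the 2-cell stage 14 rose and 3 fell (16 and 3 adjusted over the list alone). Slc34a2, Pramel7 and Tmem92 went from the floor to 12.3 ± 2.9, 8.62 ± 1.87 and 7.40 ± 0.0842 FPKM (median 0.63, camera adjusted p = 5.29e-10, and adjusted p = 0.467 with an estimated correlation). Oocyte-specific and maternal-effect genes fell in 35 of 41 cases and rose in 1 (35 and 1 adjusted over the list alone, median −2.52, camera adjusted p = 7.03e-12, and adjusted p = 0.467 with an estimated correlation). Nucleolar genes rose in 17 of 60 cases and fell in 13 (20 and 13 adjusted over the list alone), with Polr1c at 2.71 ± 0.19 and Rrp9 from the floor to 8.42 ± 0.55 FPKM (median 0.07, camera adjusted p = 0.00351, adjusted p = 0.869 with an estimated correlation, 35 higher and 8 lower before the factor). Meiotic genes fell in 26 of 39 cases and rose in 3 (27 and 3 adjusted over the list alone), with the securin gene Pttg1 at −3.55 ± 0.22 and Bub1b from 20.3 ± 2.44 FPKM to the floor (camera adjusted p = 0.000399, adjusted p = 0.825 with an estimated correlation).

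Translational control genes fell in 16 of 29 cases and rose in 0 from the WT 1-cell to the WT 2-cell stage (1 when adjusted over the list alone, and 21 genes at an unadjusted limma p under 0.05 in either direction), with a camera adjusted p of 0.00156, or 0.0931 before the factor. Chromatin modifiers fell in 24 of 48 and rose in 2 (median −0.66, camera adjusted p = 0.0148, or 0.225 before the factor), and lineage regulators rose in 7 of 22 and fell in 4 (median 0.02, camera adjusted p = 0.0208). With an estimated correlation the adjusted p was 0.825, 0.869 and 0.825 for these lists. Without a camera call, oxidative phosphorylation genes split into 15 higher and 28 lower of 83 (median −0.07, camera direction up). Translation factors split into 10 and 24 of 61, proteasome genes into 6 and 16 of 34, cleavage and polyadenylation factors into 8 and 12 of 30 (median 0, mean −0.19, camera direction up). Deadenylation genes split into 1 and 15 of 39, poly(A)-binding genes into 2 and 4 of 8, p53 targets into 5 and 5 of 25, early-response genes into 2 and 4 of 17 and histone genes into 3 and 8 of 38. Of reference genes 8 rose and 6 fell of 19 (median −0.03, mean 0.10). Of the cumulus, sperm and blood markers 0 of 11, 1 of 6 and 0 of 10 rose, with 2, 2 and 1 at an unadjusted p under 0.05, and 2, 1 and 1 fell. Before the factor more genes rose than fell in several of these lists, with 41 higher and 10 lower for oxidative phosphorylation, 29 and 15 for translation factors, 12 and 11 for proteasome genes, 14 and 5 for cleavage and polyadenylation factors, 11 and 10 for deadenylation genes and 4 and 3 for poly(A)-binding genes. In all, 1068 genes were called higher and 3274 lower, 580 and 2198 at least 2-fold. This compares with a median log2 ratio of −0.83 (0.563-fold) over 4551 genes as deposited and 0.17 before the factor. Before the factor 2369 were higher and 1688 lower. The share of higher calls was 24.6% as deposited, 58.4% before the factor, 58.2% with median-ratio size factors (2347 and 1685) and 43.1% with quantile normalization (2255 and 2972).

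Transcripts were then compared by their fate in WT embryos. Transcripts gained in WT 2-cell embryos, 44 to 59 genes in the 4 combinations of libraries, were lower in KO 2-cell embryos, with medians of −3.27 to −1.85 and a mean of medians of −2.46 on the log2 scale. On average 90.4% of them were at least 2-fold lower. Before the factor the mean of medians was −2.90. Transcripts lost early in WT, 3574 to 4001 genes, were higher in KO 1-cell embryos, with medians of 0.69 to 1.35 and a mean of 1.00. Transcripts kept in WT, 73 to 100 genes, had a mean of medians of 0.69 there (0.44 to 0.82). Transcripts lost late had 0.73 (0.28 to 1.10), with 0.90 and 1.10 from WT replicate 1 (93 genes) and 0.28 and 0.63 from WT replicate 2 (20 genes). The excess of lost-early over kept transcripts was 0.32 (0.19 to 0.52). These classes carry the general shift of the 1-cell stage. Before the factor the medians were 0.04 for lost early, and the direction turned for kept (−0.20) and lost late (−0.28). With classes also formed before the factor, they were 0.48 for lost early (0.42 to 0.51, 565 to 593 genes), 0.02 for kept and −0.03 for lost late. At the 2-cell stage lost early and kept transcripts had medians of 0 and 0.06, the first of these at the floor in most libraries. With classes also formed before the factor, lost early transcripts were lower in KO 2-cell embryos, at −0.43 (−0.53 to −0.32), and 36.7% were at least 2-fold lower against 11.7% higher. Lost late transcripts had 0.23, with 0.37 and 0.58 from WT replicate 1 and 0 and −0.01 from WT replicate 2, and 0.51 (0.31 to 0.72) with classes also formed before the factor.

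**Figure D4:**
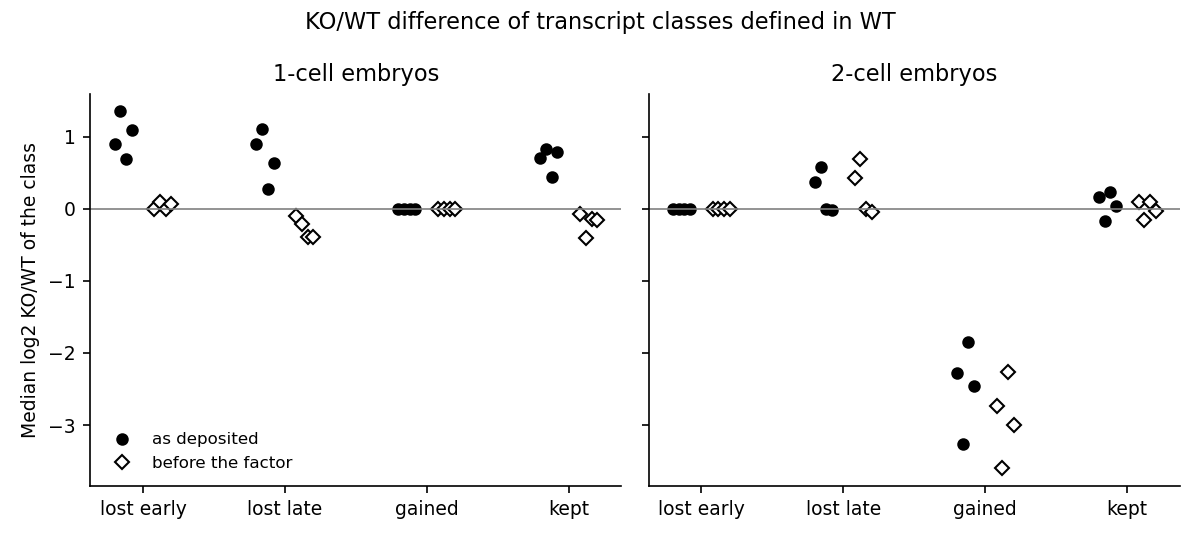
Median log2 ratio of KO to WT (vertical axis) of transcript classes defined in WT embryos, at the 1-cell and the 2-cell stage (horizontal axis); points are the 4 combinations of libraries, filled as deposited and open before the library factor. Gained transcripts lie between −3.27 and −1.85 at the 2-cell stage as deposited, and lost-early transcripts between 0.69 and 1.35 at the 1-cell stage as deposited, with a mean of 0.04 before the factor, where part of them is at the common floor.

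Calls of both embryonic stages were compared among genes above the floor in at least 1 library at each stage, because other genes have no difference at a stage as deposited. This restriction was chosen after seeing the data. The comparisons share no library, only the fit. Of 6163 such genes 813 were called higher in KO at both stages, against 647.6 for independent lists (Fisher's exact test, two-sided, adjusted over 9 overlaps p = 1.4e-63, odds ratio 10.3). Before the factor 294 of 5654 genes were shared against 148.8 (adjusted p = 1.37e-39, odds ratio 3.21), and with quantile normalization 376 against 244.9 (adjusted p = 2.99e-25). Without the restriction the latter was 378 against 346 (adjusted p = 0.112). Rn45s, Hist1h2bc, Lsm5, Tm2d1 and Ndufb3 were among the 8 largest rises at both stages. Genes called lower at both stages numbered 7 against 1.6 as deposited (adjusted p = 0.00069, but 1 against 0.5 with adjusted p = 0.958 among genes changed at least 2-fold), 75 against 44.1 before the factor (adjusted p = 1.39e-06) and 181 against 143.8 with quantile normalization (adjusted p = 0.000967). Without the restriction this last number turned to 208 against 356.3. Genes higher at the 1-cell stage and lower at the 2-cell stage numbered 667 against 774.7 as deposited (adjusted p = 8.91e-17) and 153 against 180.8 before the factor (adjusted p = 0.0224). They numbered 260 against 256.8 among genes changed at least 2-fold and 228 against 208.8 with quantile normalization (adjusted p = 1 and 0.222), so this direction depends on the setting. Across these genes the log2 fold changes of both stages had a Spearman's rho of 0.28. Genes are not independent replicates, and calls at both stages depend on expression level and on 1 shared variance per gene, for which overlaps were not matched.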

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

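The tests of how the KO effect differed between stages were fixed before the data were examined, and the values before the library factor were chosen after the result was seen. Between GV oocytes and 1-cell embryos the KO effect differed by a limma interaction term for 4374 genes with a rise and 97 with a fall relative to WT. Before the factor these numbers were 253 and 57. The share of rises was 97.8% as deposited, 81.6% before the factor, 74.8% with median-ratio size factors and 67% with quantile normalization. Without WT GV replicate 1 the numbers were 2786 and 148, without WT 1-cell replicate 2 they were 1846 and 43, and without KO 1-cell replicate 2 they were 2642 and 56. The falls numbered 202 without WT GV replicate 2, 55 without WT 1-cell replicate 1, 337 without KO GV replicate 1 and 372 without KO GV replicate 2. Rn45s differed as well (fitted 11.32), with no fixed size since it was at the floor in WT 1-cell embryos. The named genes with the largest other rises in log2 effect were Hist1h2bc (5.20), Cox7c (5.09), Tm2d1 (4.54) and Psma5 (4.30), and those with the largest falls were Cdk1 (−1.25), Sec62 (−1.16), Atp6v1g1 (−1.06), Cox4i2 (−1.05, WT 1-cell embryos at the floor) and Sod1 (−0.84). Before the factor the differences of Cdk1 (−1.20, adjusted p = 0.114) and Cox4i2 (−0.33, adjusted p = 0.46) no longer passed, nor did they with median-ratio size factors (−1.06 and −0.28) or quantile normalization (−1.77 and −0.64). That of Cdk1 also did not pass without WT GV replicate 1 (−1.12, adjusted p = 0.0521). For Sod1 the adjusted p was 0.076 without WT GV replicate 1, 0.0659 without WT GV replicate 2, 0.077 without WT 1-cell replicate 1, 0.0559 without KO GV replicate 1, 0.0681 without KO GV replicate 2 and 0.103 without KO 1-cell replicate 2.

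Between 1-cell and 2-cell embryos the KO effect rose for 27 genes and fell for 4028. Before the factor it rose for 668 and fell for 1785. The share of rises was 0.7% as deposited, 27.2% before the factor, 30.4% with median-ratio size factors and 61.6% with quantile normalization. The last of these was not restricted to genes above the floor. Without WT 1-cell replicate 2 it rose for 42 and fell for 2411, without WT 2-cell replicate 2 it fell for 2370, and without KO 2-cell replicate 2 it rose for 86. The named genes with rises were Vaultrc5 (3.19), the minor spliceosome RNA Rnu11 (2.90), the thymosin gene Tmsb4x (2.5), Pabpn1l (1.97) and Dazl (1.73). Rnu11 and Tmsb4x were at the floor in all 1-cell embryos, and Rnu11 in WT 2-cell embryos. Pabpn1l was at or near it in all 2-cell embryos, so these fitted values have no fixed size. Among the largest falls were those of Rpl18 (−5.62), Psmb1 (−5.55), Snrpc (−5.55) and Psma5 (−5.34).

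Rn45s was at the floor in all WT embryo libraries and at 4062 ± 1100 and 1464 ± 197 FPKM in KO 1-cell and 2-cell embryos, while oocytes held 5053 ± 1420 FPKM in WT and 4273 ± 2580 in KO. A failed estimate of the authors' software at this locus would leave other genes at the floor in 1 library of a group and above 100 FPKM in the other, where neither genotype nor stage differs. This was the case for 3 genes, Scarna17 in WT 1-cell (1 and 165.8 FPKM) and KO 1-cell embryos (296.4 and 1), Rps27 in KO oocytes (298.9 and 1) and Scarna2 in KO 2-cell embryos (1 and 146.5). The bounds set in advance were at least 5 genes for a failed estimate and 0 against it, so with 3 genes a failed estimate and a difference between genotypes cannot be told apart for Rn45s. Priming of this ribosomal RNA precursor by oligo-dT was not tested.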

How the results depend on the processing

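Chosen after seeing the data were the values before the library factor, no pseudocount, genes above the floor in every library of the contrast, classes formed before the factor, and long transcripts. The other alternatives were fixed before. Numbers of called genes are given as higher and lower, and unless stated otherwise the cause was not tested. Quantile normalization gave 1 and 1 at the GV stage, 1445 and 1856 at the 1-cell stage, 2705 and 2169 at the 2-cell stage, and 3775 and 2690 from WT GV to 1-cell. It also gave 2255 higher from WT 1-cell to 2-cell, 656 and 323 for the GV to 1-cell interaction and 3550 and 2211 for the 1-cell to 2-cell interaction. Median-ratio size factors gave 107 higher at the GV stage, 749 and 327 at the 1-cell stage, and 993 and 2429 from WT GV to 1-cell. They gave 2347 and 1685 from WT 1-cell to 2-cell, 217 for rises in the GV to 1-cell interaction and 743 and 1703 for the 1-cell to 2-cell interaction. Before the factor there were 191 lower at the GV stage, 831 and 255 at the 1-cell stage, 979 and 2383 from WT GV to 1-cell, and 2369 and 1688 from WT 1-cell to 2-cell. The interactions had 253 and 57, and 668 and 1785. This setting removes factors that differ between groups of embryos and also raises the floor, and these parts were not separated. At the GV stage the factor is 1. With only the groups compared the limma numbers were 0 and 0 at the GV stage (496 genes at an unadjusted p under 0.05), 608 and 1 at the 1-cell stage, 354 and 595 at the 2-cell stage and 2103 and 58 for the GV to 1-cell interaction. On simulated data this fit recovered 0 of 100 genes changed 4-fold at the GV and 1-cell stages and 12 at the 2-cell stage, and it also ended the call of Pabpn1l in oocytes (adjusted p = 0.592), so its low numbers follow from its few degrees of freedom. A mean of at least 5 FPKM left 0 and 2 at the GV stage, 5481 lower from WT GV to 1-cell, 554 higher from WT 1-cell to 2-cell and 7 falls in the GV to 1-cell interaction. Genes above the floor in every library gave 21 and 40 at the GV stage, 796 lower at the 2-cell stage, 1 and 6163 from WT GV to 1-cell, and 444 higher from WT 1-cell to 2-cell. They gave 8 falls in the GV to 1-cell and 2018 in the 1-cell to 2-cell interaction. Both settings test fewer genes. Without the intensity trend 6 and 8 were called at the GV stage and 62 falls in the GV to 1-cell interaction. Rises in the 1-cell to 2-cell interaction numbered 43 with a pseudocount of 0.1 and 46 without one. The filter at 1 FPKM removed no gene, so leaving it out is no test. With 0 ERCC entries, ERCC scaling was not run.

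For transcript classes at the 1-cell stage, the median of lost early transcripts was 0.16 with quantile normalization, 0.01 with median-ratio size factors, 0.04 before the factor, 0.06 before the factor among long transcripts and 0.48 with classes also formed before the factor. In the same order lost late transcripts turned to −0.43, −0.32, −0.28, −0.34 and −0.03. Kept transcripts turned to −0.34, −0.23, −0.20 and −0.24, with 0.02 in the last setting. Gained transcripts were at −0.14 with quantile normalization. At the 2-cell stage lost early transcripts were at −0.01 with a minimum of 20 FPKM, 0.10 with quantile normalization and −0.43 with classes also formed before the factor. Gained transcripts kept their direction at the 2-cell stage in all settings run. Of 174 values of named genes, 156 kept direction and side of the threshold before the factor, 155 with median-ratio size factors, 146 with quantile normalization and 112 with only the groups compared, where 62 kept the direction without the call. Directions turned for Esr2 at the 1-cell stage (−0.22 with quantile normalization, −0.15 with median-ratio size factors, −0.11 before the factor), Cyp19a1 (−0.27, −0.20 and −0.16), Pecam1 (−0.14, −0.08 and −0.04), Cml2 (−0.06 with quantile normalization), Paip2b (−0.08 with quantile normalization) and Btg4 from WT GV to 1-cell (0.56, 0.78 and 0.79). Set tests were called in 60 of 147 cases, of which 36 were called in the same direction before the factor, 32 with quantile normalization and 35 with median-ratio size factors, 0 in the opposite direction, and 0 with an estimated correlation, where the lowest adjusted p was 0.221.

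Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 151 to 360 higher and 328 to 433 lower at the GV stage, 3422 to 6684 and 6 to 15 at the 1-cell stage, and 464 to 581 and 834 to 1214 at the 2-cell stage. It gave 2 to 5 and 9329 to 9581 from WT GV to 1-cell, 806 to 1123 and 2387 to 3151 from WT 1-cell to 2-cell. For the interactions it gave 1846 to 5942 and 43 to 372 from GV to 1-cell, and 20 to 86 and 2370 to 5577 from 1-cell to 2-cell. With the replicate number as a block the numbers were 52 and 85, 5750 and 8, 761 and 1254, 4 and 9689, 1044 and 3138, 3779 and 85, and 27 and 3688 in the same order. With it, all 60 set calls held. The block ended the calls of Fam25c (−0.89, adjusted p = 0.0657), Gm9781 (adjusted p = 0.052) and Hist4h4 (adjusted p = 0.0641) at the GV stage, Cox5a at the 1-cell stage (adjusted p = 0.0632) and Sod1 in the interaction (adjusted p = 0.0546), and no other call of a named gene. Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated at −0.40 to 0.17 over 15 pairs of groups. Levels under 1 FPKM on the deposited scale were not measured. This is a higher level before the factor in embryos than in oocytes. Falls of genes near the floor could thus not be seen.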

Other observations

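Of the tests below, the ratio of all genes without the factor and, for the loss sets, the test of long transcripts were chosen after the result was seen, while the bounds for the other tests were set before. Values before the factor and the restriction to long transcripts were chosen after seeing the data. Relative to the change in WT, the camera test called 7 of 21 gene lists for the KO effect between GV oocytes and 1-cell embryos and 11 of 21 between 1-cell and 2-cell embryos, and 0 of either with an estimated correlation. From GV oocytes to 1-cell embryos the KO effect rose for 28 of 34 proteasome genes (30 adjusted over the list alone), with Psma5 (4.30 ± 0.34 SE on the log2 scale), Psmb1 (3.81 ± 0.34) and Psmb7 (3.24 ± 0.28) as examples. It fell for 0 of them (31 at an unadjusted limma p under 0.05, camera adjusted p = 1.53e-06). Before the library factor 6 of these genes passed and the list kept its camera call (median 0.52, adjusted p = 4.72e-10). Oxidative phosphorylation genes rose in 52 of 83 cases and fell in 1 (53 and 1 adjusted over the list alone), with Cox7c (5.09 ± 0.48), Ndufb3 (4.08 ± 0.36) and Sdhd (3.57 ± 0.33) as examples. Their camera adjusted p was 0.00141, or 0.0037 before the factor with 10 higher and 1 lower. With an estimated correlation the adjusted p was 0.661 and 0.693 for these lists. Among common reference genes B2m (2.94 ± 0.39) and Ppia (2.83 ± 0.34) rose, also before the factor (2.08 and 1.87). The KO effect also rose for 38 of 85 ribosomal protein genes (41 adjusted over the list alone, median 1.02, camera adjusted p = 0.0211) and for 23 of 41 oocyte-specific and maternal-effect genes (27 adjusted over the list alone, median 0.96, camera adjusted p = 0.0134). Before the factor these 2 calls ended (adjusted p = 0.153 and 0.582), and adjusted p = 0.693 with an estimated correlation for both. Camera placed 3 sparse lists below other genes. These were 2-cell-stage transient genes (median 0, mean 0.23, adjusted p = 0.00096), early-response genes (0.05 and 0.34, adjusted p = 0.00243) and cumulus markers (0.06 and 0.23, adjusted p = 0.00758), with 0.582, 0.265 and 0.582 before the factor and adjusted p = 0.661 with an estimated correlation for each.

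From 1-cell to 2-cell embryos the KO effect fell for 75 of 85 ribosomal protein genes (78 adjusted over the list alone, median −2.56, camera adjusted p = 6.6e-19), including Rpl18 (−5.62 ± 0.31) and Rps3 (−4.65 ± 0.29). It fell for 54 of these genes before the factor (camera adjusted p = 7.61e-15). It fell for 45 of 60 nucleolar genes (49 adjusted over the list alone, median −1.67, camera adjusted p = 3.34e-09), including Ebna1bp2 (−3.73 ± 0.27), Nhp2 (−3.68 ± 0.29) and Ltv1 (−3.51 ± 0.31). Before the factor it fell for 38 of the nucleolar genes and rose for 1 (camera adjusted p = 5.14e-12). It fell for 29 of 34 proteasome genes (31 adjusted over the list alone, camera adjusted p = 1.22e-09) and for 63 of 83 oxidative phosphorylation genes (66 adjusted over the list alone, camera adjusted p = 7.9e-09). It also fell for 16 of 27 transient genes of the 2-cell stage (16 adjusted over the list alone, camera adjusted p = 0.00618). Before the factor it fell for 21, 31 and 15 genes of these lists and rose for 1, 1 and 0, with camera adjusted p of 1.91e-08, 0.00024 and 1.13e-06. With an estimated correlation the adjusted p was 0.482 for the ribosomal, proteasome and oxidative phosphorylation lists. It was 0.529 for the nucleolar list and 0.614 for the transient genes. The KO effect fell as well for 36 of 61 translation factors (43 adjusted over the list alone, median −1.08, camera adjusted p = 0.000934), 19 of 30 cleavage and polyadenylation factors (20, −1.59, 0.00618), 20 of 39 meiotic genes (23, −1.16, 0.0171) and 13 of 19 reference genes (13, −1.51, 0.0171). Before the factor 21, 12, 11 and 6 fell and 5, 1, 5 and 2 rose, with camera adjusted p of 0.0103, 0.00493, 0.23 and 0.189. Camera placed blood markers (median 0, mean 0.01, adjusted p = 0.000155) and cumulus markers (0 and −0.13, adjusted p = 0.006) above other genes, with 0.0748 and 0.2 before the factor. With an estimated correlation the adjusted p of these 6 lists was 0.614, 0.578, 0.733, 0.578, 0.358 and 0.395.

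Among genes with at least 50 FPKM in oocytes and without the factor, the KO effect at the 1-cell stage was higher for transcripts with larger loss in WT. The means of medians over 4 combinations of libraries were 0.67 for over 8-fold loss (0.51 to 0.80), 0.53 for 4 to 8-fold (0.51 to 0.57), 0.29 for 2 to 4-fold (0.23 to 0.40), 0.18 for 1 to 2-fold (0.09 to 0.27) and −0.05 for transcripts not lost (−0.07 to −0.01). With loss from WT replicate 2 and KO replicate 2 the first step did not hold, at 0.508 against 0.517. Transcripts lost at least 4-fold stood 0.64 above those not lost (0.58 to 0.70), against −0.02 in simulated data with no changed gene.

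Transcripts lost early in WT were higher in KO 1-cell embryos than transcripts kept in WT, by 0.32 as deposited (0.19 to 0.52 over 4 combinations of libraries), 0.24 without the library factor (0.08 to 0.50) and 0.30 also restricted to long transcripts (0.15 to 0.56). Each lies between the bounds for and against its cause, so a higher RNA yield for all transcripts, the factor and transcript length stay open. Without the factor, lost early medians with KO replicate 1 were 0, at the floor, so these tests cannot decide. The general excess of KO over WT follows the factor, since the median log2 ratio over 6227 genes was 1.04 with and 0.01 without it. Whether the factor carries RNA content per embryo stays open. With classes also formed before the factor, lost early had 0.48 (0.42 to 0.51) and kept 0.02 (−0.03 to 0.06). This and, for the loss sets without the factor, 0.64 (0.58 to 0.70) argue against the factor or a common yield, which shift both sets alike. Among transcripts of at least 2000 bases, 0.69 (0.63 to 0.72) argues against transcript length as the whole cause. A technical property of both WT 1-cell libraries stays open, as loss measured to WT 2-cell embryos left 0.31 (0.26 to 0.41). Retention of maternal transcripts in KO was not tested. At the 2-cell stage, with classes formed before the factor, lost late transcripts had 0.51 (0.31 to 0.72). Lost early ones had −0.43 (−0.53 to −0.32), but may include genes transcribed anew. Of 41 oocyte-specific genes 16 were higher and 3 lower (median 0.73). Nor was a change of poly(A) tail length tested, which would alter oligo-dT priming without a change in RNA amount.

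Transcripts gained in WT 2-cell embryos were lower in KO 2-cell embryos, by a mean of medians of −2.46. The values argue against the factor as the cause, with −2.90 (−3.59 to −2.26) without it, and against transcript length, with −2.80 (−3.47 to −2.29) among transcripts of at least 2000 bases. Dilution by maternal transcripts retained in KO would lower kept transcripts as much as gained ones. The difference of gained minus kept transcripts, −2.90 (−3.43 to −2.35), argues against this. A weaker or later activation of the embryonic genome in KO is a hypothesis that was not tested here. Slower development, a different collection time or culture of the KO embryos stays open, because no other time point was sampled.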
